A study of Mus musculus with 12 samples.

How the data were processed

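RNA sequencing was deposited for 12 mouse libraries in 3 groups of 4, labelled WT, S370A and S370D. The labels describe fibroblasts from separate E13.5 embryos, grown in culture, in which the tail of the lipid phosphatase Pten is wild type or carries a change of serine 370 to alanine or to aspartate. Groups and replicate numbers were taken from the sample titles. The genotype field of the 4 libraries titled S370D reads S370A, while their title and source name read S370D, and the title was followed. Because of this conflict, and because the transcripts counted in these libraries do not match the cell type in the labels (values are given in the results), groups are written as the labels that the libraries carry. The point mutations themselves cannot be read from gene counts.

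Per the labels' protocols, RNA was extracted on RNeasy columns and libraries were made with a TruSeq RNA kit (version 2), which does not mark strand, so that reads of a gene and of an antisense partner are counted together. TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6, Subread and the genome build mm10 are named, with no role or order, per the submitters' processing notes. The annotation, the handling of reads that map to several places and any trimming are not given in the sources used here. The deposited table holds counts of reads per gene symbol, as whole numbers, for 24062 genes in the 12 libraries, with no normalization. Of these genes, 4232 had no count in any library. Near-identical genes such as the seminal vesicle secretory family, the paralogs Sbp and Sbpl, and the Xlr3 and mucin families are uncertain, since the treatment of shared reads is not stated.

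Library totals ran from 20.9 to 29.5 M counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings (a minimum count of 10 and a minimum total of 15) and the group as input, which left 14853 genes, and library sizes were scaled by the TMM method. A group-means model of all 12 libraries was fitted with estimateDisp and glmQLFit, and the 3 pairs of groups were compared with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 9 residual degrees of freedom. The common biological coefficient of variation was 0.335 and the median per gene was 0.224. Standard errors and 95% intervals of log2 fold changes come from that model. CPM values are counts per 1e6 counts (M), scaled by TMM, given as mean ± SD of 4 libraries unless a single library is named. Intervals around shares of counts are exact Clopper-Pearson intervals and cover counting error only.

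Before the data were examined, 28 gene lists were fixed (20 gene programmes and 8 sets of cell type markers), together with the rule for naming genes, the main test and the alternative settings. Lists with at least 5 tested members, 27 in all, were compared with the other genes by camera from limma 3.58.1, with the correlation between genes estimated for each list, and adjusted over the 27 lists. The naming rule took Pten, the 10 largest changes in each direction among called genes whose libraries did not overlap between groups, up to 4 members of a list by smallest p, and genes called in both comparisons. No gene was called, so that the names below come from Pten and from the lists. Members are named for the 6 lists with the smallest p of each comparison and where a member passed over its list alone. Adjustment over a list alone does not cover the 27 lists or the 3 comparisons. Single members can therefore pass by chance. Other names were chosen after their values were seen. Lists of secretory gland, fibroblast and epithelial genes were written after the most abundant transcripts had been seen.

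Exonic lengths came from GENCODE M21 for GRCm38, the assembly of mm10, matched by symbol for 22750 of 24062 genes (94.5%). The trend on length was measured in each library over 9210 genes with a mean log2 CPM above 3, as the Spearman correlation between exonic length and the deviation from the gene's median over libraries. Shares of counts were compared between groups by exact permutation tests, two-sided, adjusted over 15 tests, for which 4 libraries against 4 allow no p below 0.0286.

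Replicate pairs were checked for duplicates. The closest pair, S370A replicates 1 and 2, had a mean chi-square of 14.3 per gene, where counting noise alone gives about 1, and the next closest pair had 124. No pair was treated as 1 sample. Replicate numbers are not stated to mark a litter, a day or a batch, and the labels name no batch.

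The fit was tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed, 50 at each fold. The changed genes were picked from those above a minimum mean CPM. The other members of the FOXO target list were shifted by -0.5 on the log2 scale in each run. Of the genes changed 2-fold, the test recovered 42% for S370A against WT (14758 genes in that run), 44% for S370D against WT (14728 genes) and 58% for S370D against S370A (14741 genes). Of those changed 4-fold, it recovered 86%, 82% and 94% in the same order. There were 6, 3 and 5 false calls. Genes were drawn independently of each other, so that these rates do not cover genes that move together between libraries. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, other filters on low counts, a robust fit, only the groups compared, a block for the replicate number, an Xist covariate, a fold change threshold, other list tests (camera with a preset correlation of 0.01, and fry) and leaving out each library. Covariates for 2 groups of secretory genes (seminal vesicle and spermine-binding protein) and removal of the length trend were added after seeing the data. So were both together and a fit without 3 libraries that stood apart.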

Results

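Gene counts were obtained from 12 mouse RNA-seq libraries labelled as embryonic fibroblasts, with 4 libraries each for wild-type Pten (WT), for serine 370 changed to alanine (S370A) and for serine 370 changed to aspartate (S370D). Alanine cannot be phosphorylated, and aspartate carries a negative charge like a phosphate group. The series is described as addressing phosphorylation sites in the C-terminal tail of Pten, the phosphatase that opposes PI3K signalling. Total counts ran from 20.9 to 29.5 M per library, with a mean of 25.2 ± 2.59 M in WT, 25.6 ± 3.55 M in S370A and 21.6 ± 0.674 M in S370D (SD, n = 4 each). Between 16669 and 17911 genes had at least 1 count in a library. The p-values measure the spread between libraries, which the labels describe as coming from separate embryos.

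Pten (ENSMUSG00000013663.7) lies on chromosome 19 from 32757497 to 32826160 on the plus strand of GRCm38, and its annotated transcript has 9 exons. Codon 370 of 403, which reads AGT (serine) in the reference, lies in the coding part of exon 9, at 32819924 to 32819926. Pten was present at similar levels under all 3 labels. The mean was 114 ± 14 CPM in WT, 120 ± 17.2 CPM in S370A and 112 ± 1.95 CPM in S370D (SD, n = 4 each). The WT libraries held 99.9, 133, 109 and 113 CPM. The S370A libraries held 136, 130, 96.6 and 119 CPM, and the S370D libraries 110, 113, 113 and 114 CPM. The log2 fold change of Pten was 0.08 ± 0.12 (SE) for S370A against WT, with a 95% interval from -0.17 to 0.33. For S370D against WT it was -0.02 ± 0.12, with an interval from -0.27 to 0.24, and for S370D against S370A it was -0.10 ± 0.12, with an interval from -0.35 to 0.16. The edgeR adjusted p-values were 0.940, 0.968 and 0.825 in that order. With covariates for the secretory genes and the length trend removed, the values were -0.069, 0.17 and 0.24, each with the opposite sign.

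The most abundant transcripts in every library were those of secretory genes known from male accessory glands, not those of cultured fibroblasts. 9530053A07Rik held 92058 ± 60001 CPM in WT, 147997 ± 63894 CPM in S370A and 82666 ± 25984 CPM in S370D. Tgm4, the prostate transglutaminase, held 26281 ± 16755, 41227 ± 12594 and 27363 ± 8310 CPM in the same order. Pbsn, the androgen-regulated secretory protein probasin, held 11566 ± 6804, 18825 ± 2809 and 18572 ± 4419 CPM. The prostate transcription factors Nkx3-1 and Hoxb13 had means of 908 and 301 CPM over the 12 libraries. Among epithelial genes, Krt18 held 637 CPM and Epcam 294 CPM over the 12 libraries, while the mesenchymal genes Vim, Col1a1 and Thy1 held 122, 211 and 30.2 CPM and Tagln, Sparc, Col3a1 and Col1a2 held 1152, 510, 462 and 320 CPM. The median of the epithelial list lay between 117 and 156 CPM in the 12 libraries and that of the extracellular matrix list between 28.1 and 59.4 CPM. Together, the 3 lists of secretory and prostate identity genes took 29.6 ± 3.46% of counts in WT, 26.6 ± 1.42% in S370A and 23.8 ± 2.95% in S370D (SD, n = 4 each). The lowest library was S370D replicate 4 with 19.7% (95% interval 19.69 to 19.73%) and the highest was WT replicate 3 with 33.7% (33.70 to 33.74%). Xist had between 0 and 4 counts per library, and the Y-linked genes Ddx3y, Kdm5d and Uty had means of 48.6, 21.5 and 34.4 CPM, with values in all 12 libraries.

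**Figure D1:**
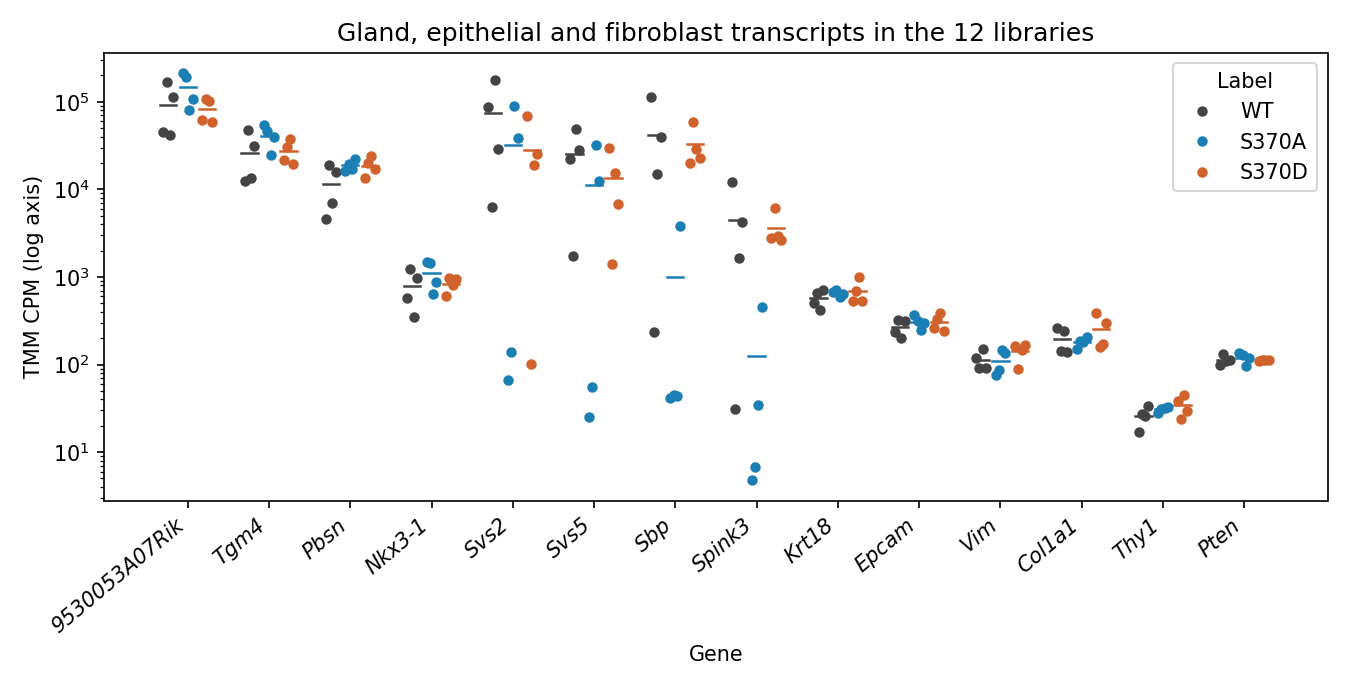
TMM-scaled CPM (log axis) of 14 genes, with 1 point per library, a horizontal line at the mean of each label's 4 libraries, and colours for WT, S370A and S370D. Secretory genes lie above Vim, Col1a1 and Thy1 in most libraries, and Svs2 spans 66.3 to 176377 CPM, while Pten lies between 96.6 and 136 CPM in all 12.

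Several secretory genes differed widely between libraries of one label. Svs2, a seminal vesicle secretory protein gene, ranged from 6308 to 176377 CPM in WT, from 66.3 to 88664 CPM in S370A and from 101 to 68360 CPM in S370D. S370A replicates 1 and 2 held 66.3 and 140 CPM and S370D replicate 2 held 101 CPM. The spermine-binding protein gene Sbp held 41851 ± 49858 CPM in WT, 991 ± 1895 CPM in S370A and 32783 ± 18099 CPM in S370D. Sbp, Sbpl and Spink3 together took 4.44 ± 5.27% of counts in WT, 0.115 ± 0.218% in S370A and 3.73 ± 1.98% in S370D. Single libraries carried the first 2 means, since WT replicate 1 held 11.9% and the other WT libraries 0.0269, 1.65 and 4.14%, and S370A replicate 4 held 0.441% and the other S370A libraries at most 0.00793%. The exact permutation p of S370D against S370A was 0.0286, the smallest that 4 against 4 libraries can give, and every S370D library lay above every S370A library. It was 0.286 after adjustment over 15 tests. The total share of the secretory and identity genes gave an exact p of 0.0571 for S370D against WT (adjusted p = 0.286). On the first principal component, which carried 57.0% of the variance of the 1000 most variable genes, S370A replicates 1 and 2 scored 80.8 and 79.5, WT replicate 2 scored 38.4 and all other libraries scored at or below 3.00.

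S370D replicate 3 stood apart in the length of its transcripts. Its deviations from the median library were lower the longer the gene, with a Spearman correlation of -0.651 across 9210 genes, which are not independent replicates. The other 11 libraries had values from -0.152 to 0.317. With the genes in 10 groups of equal size by length, the shortest group (median length 1471 bases) lay 0.61 above the median library on the log2 scale in S370D replicate 3, and the longest group (12847 bases) lay at -0.55. The androgen receptor gene Ar held 1.44 CPM in this library and 15.1 to 34.4 CPM in the others. The mean correlation was 0.138 in WT, 0.010 in S370A and -0.121 in S370D. The exact permutation p of the 3 pairs of labels ran from 0.286 to 0.714 (adjusted p from 0.506 to 0.893), and with 4 against 4 libraries a difference is not ruled out.

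**Figure D2:**
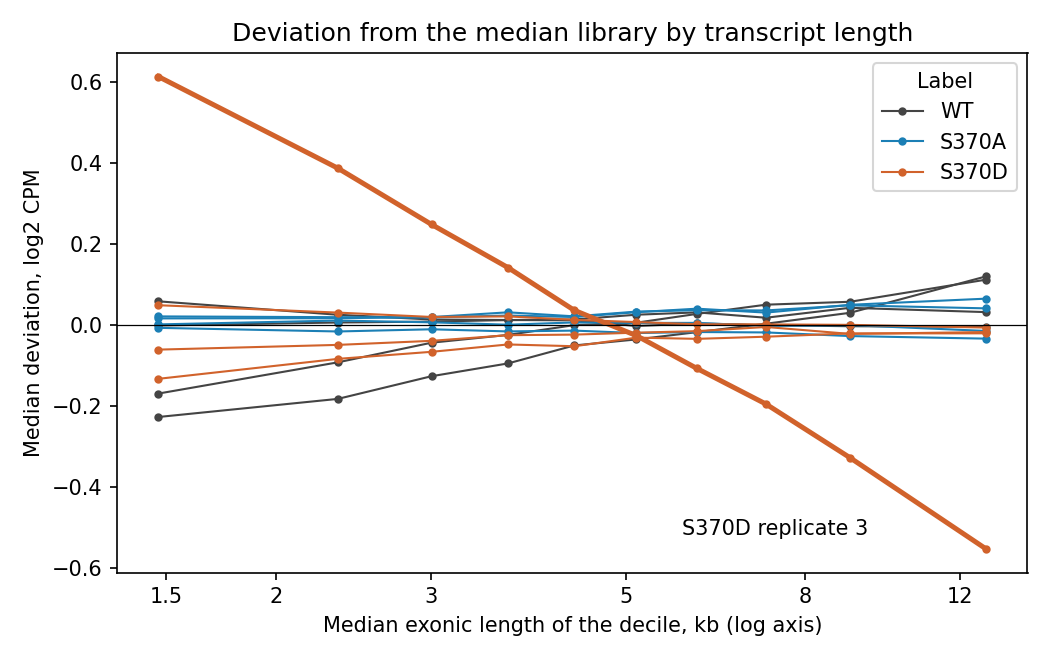
Median deviation of each library from the gene's median over libraries (log2 CPM) in 10 groups of genes by exonic length (kilobases, log axis), with 1 line per library coloured by label. S370D replicate 3, the thick line, goes from 0.61 in the shortest genes to -0.55 in the longest.

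The comparison of S370A with WT asks how gene expression differs when residue 370 cannot be phosphorylated. Nupr1, which encodes a stress-induced regulator, held 6.94 ± 4.33 CPM in S370A and 82.2 ± 67.2 CPM in WT, a log2 fold change of -3.56 ± 0.82 (SE). It was the only member that passed in the list of ATF4 targets and amino acid supply when adjusted over the list alone (adjusted p = 0.0286), and did not pass over all genes (edgeR adjusted p = 0.940). WT replicate 2, which like S370A held little Sbp, had 5.44 CPM of Nupr1. In the unfolded protein response list, 16 of 20 members were higher in S370A and 6 had an unadjusted p under 0.05. None passed over all genes or over the list alone. The disulfide isomerase Pdia6 held 1736 ± 148 CPM in S370A and 1077 ± 344 CPM in WT, a log2 fold change of 0.69 ± 0.22. The chaperone Hsp90b1 had a log2 fold change of 0.81 ± 0.27, Pdia3 one of 0.48 ± 0.17 and Calr one of 0.59 ± 0.21. As a set, the list did not pass (camera adjusted p = 0.933). Its median log2 fold change was 0.25, and went from 0.16 without WT replicate 3 to 0.42 without WT replicate 1.

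The other lists with the smallest p for S370A against WT did not pass either. In the list of sterol and fatty acid synthesis genes 25 of 31 members were higher, with a median log2 fold change of 0.17 and an adjusted p of 0.933 by camera, and no member passed over the list alone. Its members with the smallest p were Srebf1, the sterol regulatory transcription factor, at 0.36 ± 0.13 on the log2 scale, Sqle at 0.45 ± 0.20, Fdps at 0.41 ± 0.21 and Msmo1 at 0.29 ± 0.16. Against the same WT libraries, 26 of 31 members were higher in S370D also (median 0.18, camera adjusted p = 0.999). Without S370D replicate 1 that median was 0.0086. All 11 skeletal muscle markers were lower in S370A (median -1.19), with Neb at -1.27 ± 1.02, Ckm at -0.86 ± 0.71, Mylpf at -1.14 ± 0.99 and Ttn at -1.35 ± 1.19. Epithelial and mesothelial markers were higher for 13 of 16 members (median 0.20), among them Cldn4 at 0.45 ± 0.25, Upk1b at 0.33 ± 0.22 and Cldn7 at 0.25 ± 0.18, with Grhl2 at -0.16 ± 0.12. Of the positional homeobox factors 25 of 41 were lower. Six2 was at -2.90 ± 1.11, Six1 at -1.35 ± 0.52, Alx4 at -1.51 ± 0.73 and Hoxa6 at 0.81 ± 0.43, and the list had a median of -0.30. Six2 lay near the floor, at 0.162 ± 0.155 CPM in S370A and 1.25 ± 1.57 CPM in WT. So did Alx4, at 0.384 and 1.11 CPM, and Hoxa6, at 0.694 and 0.394 CPM in the same order. Endothelial markers were lower for 13 of 14 members, with Erg at -0.56 ± 0.35, Flt1 at -0.49 ± 0.31, Tie1 at -0.45 ± 0.32 and Sox17 at -0.41 ± 0.35. With covariates for the secretory genes Six2 was at 0.88, Six1 at 0.16 and Tie1 at 0.0048, and with the length trend removed as well Hoxa6 was at -0.052, Upk1b at -0.038 and Flt1 at 0.0010, so that the direction of these 6 genes turned. The endothelial list turned its direction with these covariates, with both corrections and in a fit of 9 libraries (without S370A replicates 1 and 2 and S370D replicate 3), and the homeobox list turned with the 9 libraries. Leaving out 1 library moved the medians of these lists. That of the muscle list ranged from -3.98 without S370A replicate 3 to -0.20 without WT replicate 4, with 12 members tested in both of these fits. That of the homeobox list ranged from -0.49 to -0.090 and that of the endothelial list from -0.39 to -0.027, the ends being without S370A replicate 3 and without WT replicate 3. The epithelial median ranged from 0.086 without WT replicate 3 (17 members) to 0.29 without WT replicate 2 and the lipid synthesis median from 0.11 without S370A replicate 1 to 0.23 without WT replicate 1. The camera adjusted p of the 27 lists ran from 0.933 to 0.952.

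Across the 14853 genes tested, edgeR called 0 for S370A against WT, with 413 genes at an unadjusted p under 0.05 where 743 would be found by chance, and a smallest adjusted p of 0.940. In 209 genes (1.41%) the 4 libraries of one label all lay above the 4 of the other, where chance gives 2.86%. DESeq2 called 9 genes, all lower in S370A, and limma-voom called 0, with 365 at an unadjusted p under 0.05. The DESeq2 calls included Nupr1 and Sbpl, the latter named after its values were seen. The median 95% interval of a log2 fold change reached 0.45 to either side.

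The comparison of S370D with WT asks how expression differs when residue 370 is replaced by an acidic residue. Targets of the FOXO transcription factors, which AKT keeps out of the nucleus when PI3K signalling is high, lay lower in S370D for 18 of 24 members, with a median log2 fold change of -0.21. The insulin receptor gene Insr held 54.5 ± 8.47 CPM in S370D and 77.0 ± 5.97 CPM in WT, a log2 fold change of -0.50 ± 0.11 (SE). The transcriptional repressor gene Bcl6 held 11.1 ± 2.95 CPM and 20.3 ± 4.70 CPM, a log2 fold change of -0.88 ± 0.21. In both genes every S370D library lay below every WT library. Insr and Bcl6 passed when adjusted over the list alone (adjusted p = 0.0193 for each), and 0 members passed over all genes (edgeR adjusted p = 0.713). Adjustment over the list alone does not cover the number of lists and comparisons tested. Klhl24 was at -0.59 ± 0.21, and Cited2 went the other way at 0.51 ± 0.19. The list as a set missed the threshold after adjustment over the 27 lists (camera adjusted p = 0.0588). The adjusted p was 0.0216 without WT replicate 1 and 0.0261 without S370D replicate 3, the library with the length trend, and reached 0.486 without S370A replicate 3. That library is not part of this comparison, and without it the median was -0.23 with 18 of 24 members lower. The median ranged from -0.27 to -0.13 in the fits without 1 library, the ends being without WT replicate 1 and without S370D replicate 3.

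**Figure D3:**
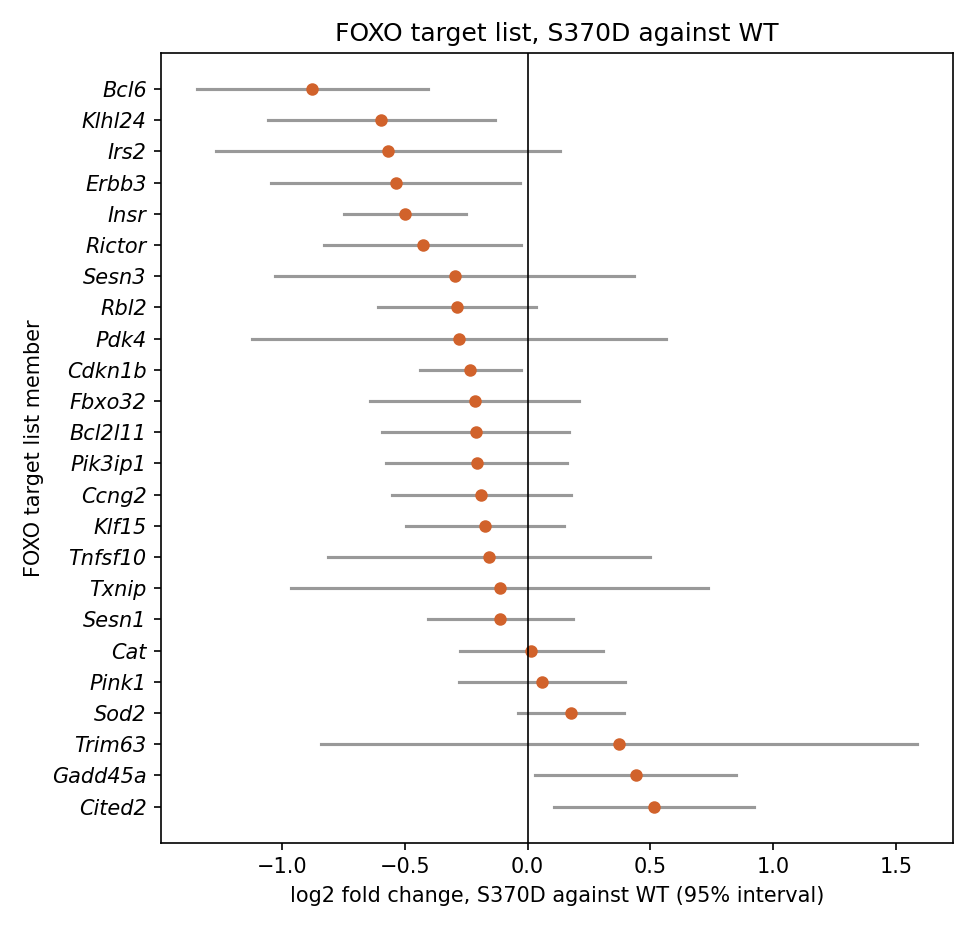
Log2 fold change of S370D against WT (x axis) for the 24 tested members of the FOXO target list (y axis, ordered by value), with 95% intervals of the edgeR fit as lines. Of the 24 points 18 lie below 0, with Bcl6 lowest at -0.88 and Cited2 highest at 0.51.

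The components of the PI3K, AKT and mTOR pathway were lower in S370D than in WT for 25 of 33 members, with a median of -0.16 (camera adjusted p = 0.430), which went to -0.087 without S370D replicate 3 and to -0.21 without S370D replicate 2. Insr, a member of this list also, passed when adjusted over the list alone (adjusted p = 0.0303). The kinase gene Akt3 was at -0.50 ± 0.19, Rictor, a subunit of the mTORC2 complex, at -0.43 ± 0.18 and the growth factor receptor gene Igf1r at -0.49 ± 0.24. Rictor held 14 CPM in S370D replicate 3 and 25.5 to 26.8 CPM in the other S370D libraries. The muscle and neural marker lists did not pass. All 11 skeletal muscle markers had a positive log2 fold change (median 1.27, adjusted p = 0.738), with Acta1 at 0.47 ± 0.17, Mylpf at 2.06 ± 1.0, Des at 0.33 ± 0.17 and Actc1 at 2.07 ± 1.09. The median of that list ranged from 0.90 without S370D replicate 4 to 2.74 without WT replicate 4, where 12 members were tested. Of the neural and neural crest markers, 15 of 17 were higher (median 1.95, adjusted p = 0.738), with the myelin protein gene Mpz at 1.64 ± 0.55, Sox2 at 0.67 ± 0.25 and S100b at 1.22 ± 0.56, and Erbb3 at -0.54 ± 0.23. None of these markers passed when adjusted over the list alone. S100b lay near the floor, at 2.23 CPM in S370D and 0.953 CPM in WT. Neural markers were also higher in S370A than in WT for 15 of 17 members (median 1.23, camera adjusted p = 0.933). Without S370A replicate 3 that median was -0.033. Erbb3 held 25.9 CPM in S370D replicate 3 and 60.1 to 66.6 CPM in the other S370D libraries.

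Epithelial markers were higher in S370D than in WT for 13 of 16 members (median 0.22, adjusted p = 0.881). The basal keratin gene Krt5 was at 0.62 ± 0.21, Krt19 at 0.57 ± 0.28, Cldn7 at 0.32 ± 0.18 and Grhl2 at -0.36 ± 0.12. In the unfolded protein response list 18 of 20 members were higher (median 0.35, adjusted p = 0.881), with Calr at 0.56 ± 0.21, Pdia6 at 0.54 ± 0.22, Pdia3 at 0.38 ± 0.17 and Sdf2l1 at 0.60 ± 0.27. Without 1 library the epithelial median ranged from 0.10 (S370D replicate 3, 17 members) to 0.35 (WT replicate 2) and that of the unfolded protein response list from 0.20 (WT replicate 3) to 0.48 (WT replicate 1). The G2/M list had 32 of 32 members higher with a median of 0.43, while the camera test, which allows for a correlation of 0.838 between its members, gave the opposite sign with an adjusted p of 0.999. S370D replicate 1 carried this difference, since without it the median was -0.95 and 3 of 32 members were higher. Mki67, named after its values were seen, held 73.1 CPM in that library and 5.61, 3.23 and 15.5 CPM in S370D replicates 2, 3 and 4, against 10.8 to 29.9 CPM in WT. All lists other than the FOXO and PI3K lists had an adjusted p of at least 0.738. Across all genes, edgeR called 0 of 14853 for S370D against WT, with 833 at an unadjusted p under 0.05 and 743 expected by chance, and a smallest adjusted p of 0.713. The 4 libraries of one label lay above all 4 of the other in 486 genes (3.27%, chance 2.86%). DESeq2 called 2 genes and limma-voom 0, with 869 at an unadjusted p under 0.05. The DESeq2 calls were AY761184, at 14.7 ± 6.07 CPM in S370D and 3.74 ± 1.64 CPM in WT, and the beta-defensin gene Defb1, at 612 ± 165 and 286 ± 66.6 CPM. The edgeR log2 fold changes were 1.97 ± 0.40 and 1.10 ± 0.23, and both genes are named here after their values were seen.

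The direct comparison of S370D with S370A asks whether the acidic and the non-phosphorylatable residue differ. Skeletal muscle markers were higher in S370D for all 11 members, with a median log2 fold change of 2.70. Mylpf, a myosin light chain gene, held 45.2 ± 30.7 CPM in S370D and 4.89 ± 7.19 CPM in S370A, a log2 fold change of 3.20 ± 1.05 (SE). Ckm, the muscle creatine kinase gene, held 71.7 ± 45.9 and 16.3 ± 17.0 CPM (2.14 ± 0.73), and the actin gene Acta1 held 457 ± 95.5 and 306 ± 44.3 CPM (0.58 ± 0.17). These 3 genes passed when adjusted over the list alone (adjusted p = 0.0462 for each) and did not pass over all genes (edgeR adjusted p = 0.724). Actc1 was at 3.07 ± 1.14. The list as a set did not pass (camera adjusted p = 0.181). S370A replicates 1 and 2 held 0.944 and 0.895 CPM of Mylpf, and S370A replicate 3 held 15.6 CPM. The median of the list was 5.63 without S370A replicate 3, where 12 members were tested, and 2.22 without S370D replicate 4.

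FOXO targets were lower in S370D than in S370A for 15 of 24 members (median -0.21, camera adjusted p = 0.118). Insr was at -0.37 ± 0.11, Klhl24 at -0.64 ± 0.21, Bcl6 at -0.59 ± 0.21 and Rbl2 at -0.39 ± 0.15, and none passed over the list alone. PI3K pathway components were lower for 23 of 33 members (median -0.15, adjusted p = 0.325), with Pik3cb at -0.59 ± 0.20, Rptor at -0.17 ± 0.07 and Akt3 at -0.45 ± 0.19. Antioxidant genes of the NRF2 list were higher for 21 of 23 members (median 0.20, adjusted p = 0.853), with glutathione reductase Gsr at 0.45 ± 0.13, Pgd at 0.20 ± 0.09, Gstp1 at 0.28 ± 0.17 and Slc48a1 at 0.16 ± 0.10. Chondrocyte and osteoblast markers were higher for 9 of 10 members (adjusted p = 0.853), with Col9a2 at 2.09 ± 0.77, Col11a2 at 0.91 ± 0.37, Sox9 at 0.39 ± 0.23 and Matn4 at 0.82 ± 0.57. Near the floor lay Col9a2 (2.81 CPM in S370D and 0.652 CPM in S370A), Col11a2 (1.43 and 0.754 CPM) and Matn4 (1.60 and 0.897 CPM). With covariates for the secretory genes and the length trend removed, Col9a2 was at -0.012, Sox9 at -0.11, Rptor at 0.061, Gstp1 at -0.13 and Slc48a1 at -0.086, so that the direction of these 5 genes turned. The NRF2 list turned its direction with both corrections and in the fit of 9 libraries, and its median ranged from 0.11 without S370D replicate 4 to 0.25 without S370A replicate 3. The median of the PI3K list ranged from -0.21 without S370A replicate 3 to -0.10 without S370D replicate 3. Neural markers were higher for 16 of 17 members (adjusted p = 0.853), with Sox2 at 0.55 ± 0.25, Sox10 at 0.99 ± 0.54 and S100b at 0.85 ± 0.55, and Erbb3 at -0.55 ± 0.23. S100b lay near the floor, at 2.23 CPM in S370D and 1.23 CPM in S370A. In S370D replicate 3 Erbb3 held 25.9 CPM, against 60.1 to 66.6 CPM in the other S370D libraries. Nupr1 (3.41 ± 0.81, adjusted p = 0.0377) and the immediate early gene Ier2 (0.52 ± 0.12, adjusted p = 0.0308) passed in their own lists when adjusted over the list alone.

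Across all genes, edgeR called 0 of 14853 for S370D against S370A, with 997 at an unadjusted p under 0.05 and 743 expected by chance, of which 631 were higher in S370D and 366 lower. The smallest adjusted p was 0.724. The 4 libraries of one label lay above all 4 of the other in 643 genes (4.33%, chance 2.86%). DESeq2 called 20 genes, 18 higher and 2 lower in S370D, and limma-voom called 0, with 1010 at an unadjusted p under 0.05. The DESeq2 calls with the largest log2 fold changes were Sbpl at 6.58, Mug1 at 6.55 and 3110079O15Rik at 5.84, all 3 named after their values were seen.

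The fold changes of both mutants against WT were correlated across genes, with r = 0.430 and a covariance of 0.0997 over 14853 genes, which are not independent replicates. Both comparisons use the same 4 WT libraries. In 50 simulations of unchanged groups that share those libraries, r averaged 0.499, with a range from 0.465 to 0.533, and the covariance averaged 0.0884, with a range from 0.0815 to 0.0978. The observed covariance exceeded the simulated mean by 0.0114. The simulations drew each gene independently, while genes of these libraries moved together. Their range is therefore too narrow to judge this excess. With the WT libraries split 2 and 2 between the comparisons, r ranged from -0.213 to 0.482 over 6 assignments, with a median of 0.0139. The covariance over these 6 assignments ranged from -0.0748 to 0.116, with a median of 0.0046. Leaving out WT replicate 4 gave r = 0.692 and leaving out S370A replicate 3 gave r = 0.12.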

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

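The tests in this part were chosen after the result was seen, except the share of lists with a negative length trend in S370D replicate 3. A library is named when its gap to the nearest of the other 3 libraries of its label, divided by the label's whole range, exceeded the 95% critical value of Dixon's test. Of 204 groups of 4 tested, 16 had such a library, where chance gives about 10.2, and 6 of the 16 were S370D replicate 3.

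S370D replicate 3 held less than the other S370D libraries of Klhl24 (33.4 CPM, others 59.6 to 64.6), Rictor (14 CPM, others 25.5 to 26.8), Erbb3 (25.9 CPM, others 60.1 to 66.6), Rbl2 (50.3 CPM, others 75.1 to 75.6) and Ar (1.44 CPM, others 20.0 to 23.7). Its ratio of Eif2s3y to Ddx3y was 1.97, against 0.835 to 1.02. S370A replicate 3 held more of 4 muscle genes, with Neb at 12.6 CPM, Mylpf at 15.6 CPM, Ttn at 14.9 CPM and Actc1 at 5.95 CPM, against at most 2.04, 2.07, 1.48 and 0.348 CPM in the other S370A libraries. The spermine-binding protein group took 0.441% of counts in S370A replicate 4, against at most 0.00793% in the others of its label, and 6.67% in S370D replicate 2, against 2.38 to 2.96%. Krt19 held 624 CPM in S370A replicate 4, against 453 to 476 CPM. Of the WT libraries, replicate 2 held 35.1 CPM of Rictor (others 29.2 to 30.1), replicate 1 held 54.7 CPM of Krt5 (others 72.8 to 75.6) and replicate 3 held 145 CPM of Hoxb13 (others 316 to 326).

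The gland transcripts appeared in libraries labelled as embryonic fibroblasts. A dependence on the Pten genotype is argued against by the WT libraries, whose mean share of 29.6% was not below that of the mutants (26.6% and 23.8%). Gland RNA carried over into fibroblasts of embryos of unselected sex is argued against by Xist, at 4 counts or fewer in each of the 12 libraries, since 12 such embryos are all male with a chance of 0.000244, though embryos selected as male escape this test. A candidate explanation that the values meet is that the counts come from adult male gland tissue and not from the labelled cultures. The median of the epithelial list lay above that of the extracellular matrix list, both fixed before the data were seen, in 12 of 12 libraries. The list of contractile genes was not part of this comparison. Its genes Tagln (mean 1152 CPM), Acta2 (956 to 1824 CPM) and Myh11 (1030 to 2312 CPM) lay above the epithelial medians. So did Dcn (306 to 726 CPM) of the matrix list. Whether a table, a label or a sample was exchanged was not tested.

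The FOXO target list lay lower in S370D than in WT libraries. The loss of long transcripts in S370D replicate 3 is argued against as the whole source, since without that library the adjusted p went from 0.0588 to 0.0261 and 19 of 24 members were lower (18 of 24 with it), although the median went from -0.21 to -0.13, and removing the length trend from all libraries left a median of -0.19 with 20 of 24 lower, at an adjusted p of 0.232. Whether an unequal mix of gland parts contributed was not settled. Covariates for the seminal vesicle and spermine-binding protein lists left the median at -0.19 (SD 0.325), from -0.21 (SD 0.332). In both fits 18 of 24 members were lower, so that these scores changed the size of the shift little. The adjusted p, not past the threshold before, became 0.251 in a fit with fewer residual degrees of freedom. Prostate and matrix genes were not covered by these covariates. Of the 35 splits of these 8 libraries, 1, the real one, gave a smallest camera p over the lists as small as 0.00218 (next 0.00350). That share is the smallest that the design allows, but the comparison was picked as the smallest of 3. For S370D against S370A the smallest camera p over the lists was 0.00437 in the real split, and other splits went down to 0.00206. By the FOXO p alone, 2 of 35 splits of S370D against S370A gave a p as small. Chance is therefore not excluded over the 3 comparisons. An effect of the S370D label stays open as a hypothesis. The camera adjusted p ranged from 0.000101 with a preset correlation to 0.486 without S370A replicate 3. The estimated correlation of the list was 0.0111, near the preset 0.01, so that the size of the correlation does not explain the lower end. At the upper end, S370A replicate 3 lies outside this comparison, and without it the median was -0.23 with 18 of 24 members lower.

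The third pattern is the length-dependent loss in S370D replicate 3. An effect of the S370D genotype is argued against by the other 3 S370D libraries, whose lowest trend was -0.117, inside the range of the WT and S370A libraries (-0.152 to 0.317). Lower depth is argued against by S370D replicate 1, which had fewer counts (20.9 M against 21.9 M) and a trend of 0.107. The trend was also measured in the 27 lists with at least 10 members with a known length. In S370D replicate 3 it was negative in 100% of lists, against at most 66.7% in each other library. With a correlation of -0.651 over 9210 genes in that library, a negative trend in most lists was close to fixed in advance. The share therefore shows that the loss was spread over these lists, and decides little about its cause. RNA degradation and the preparation of that library may each produce such a loss and were not separated.

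Counts of calls were compared with those of all 35 splits of the 8 libraries of each comparison. For genes called the real value was 0 in each of the 3 comparisons, which 35 of 35 splits meet by construction, so that this count decides nothing about chance. The highest other value was 1144 genes for S370A against WT, 1625 genes for S370D against WT and 50 genes for S370D against S370A. At an unadjusted p under 0.05, as many genes as the real 413, 833 and 997 were found in 13, 14 and 5 of 35 splits in the same order (highest other 4136, 5099 and 3832), so that chance cannot be excluded for these counts. The splits with calls point to a structure of the samples other than the label. The split with 1144 genes set WT replicates 1 and 3 with S370A replicates 3 and 4. Their medians of the extracellular matrix list were 41.8 to 59.4 CPM, against 28.1 to 32.1 CPM on the other side. The split with 1625 genes set WT replicates 1 and 3 with S370D replicates 1 and 4 (51.7 to 59.4 against 31.5 to 36.2 CPM). That with 50 genes set S370A replicates 1 and 2 with S370D replicates 2 and 3 (28.1 to 36.2 against 41.8 to 56.1 CPM). Each split thus divided the libraries by this median, which was seen after the fact. No fit held a covariate for matrix genes, and the cause was not tested. For gene lists called the real value was also 0 in each comparison, which decides as little, with a highest other value of 1, 0 and 0 lists.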

How the results depend on the processing

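The covariates for the secretory genes, the removal of the length trend, both together and the fit of 9 libraries (without S370A replicates 1 and 2 and S370D replicate 3) were chosen after seeing the data. The count of genes called by edgeR, 0 in all 3 comparisons (413, 833 and 997 at an unadjusted p under 0.05), was 0 in 78 of 81 counts under the alternatives. Those with the fold change threshold were 0 by construction, being drawn from 0 called genes. The Xist covariate rested on at most 4 counts per library and carried little beyond counting noise. The exception was DESeq2, with 9 genes for S370A against WT, 2 for S370D against WT and 20 for S370D against S370A, and the cause was not tested. The count of called lists was 0 in 58 of 63. A preset correlation of 0.01, below most of those estimated, called 7, 7 and 10 lists in the same order. Without 1 library the count of lists for S370D against WT ranged from 0 to 1, the 1 list being FOXO targets without WT replicate 1 or S370D replicate 3. The replicate block called 0 genes and 0 lists and gave r = 0.305 between the fold changes of both mutants. Same-numbered libraries had correlations from -0.258 to 0.633 (mean 0.129), over 0.1 in 6 of 12 pairs. Libraries with other numbers had correlations from -0.666 to 0.688 (mean -0.043), over 0.1 in 16 of 36 pairs. The ranges overlap, so that these values do not settle whether the numbers mark something shared. The correlation r was 0.579 with 9 libraries and 0.0139 with the WT libraries split, and ranged from 0.12 without S370A replicate 3 to 0.692 without WT replicate 4. The mean gland share stayed between 26.0 and 27.3% without 1 library.

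Pten and members named from the lists with the smallest p kept direction and side of the threshold in 1869 of 1896 values. Lists did so in 354 of 378, with 18 of the list values past the threshold only under an alternative. No named gene passed in the main fit (smallest edgeR adjusted p 0.713), so that its side of the threshold was close to fixed. The count for genes therefore mainly records direction. Some settings left out a library outside the comparison. Nupr1 and Ier2, named because they passed over their list alone, were not among these genes. Nupr1 passed under DESeq2 for S370A against WT (DESeq2 adjusted p = 0.0209, edgeR adjusted p = 0.940). It also did for S370D against S370A (DESeq2 adjusted p = 0.0342, edgeR adjusted p = 0.724). With the secretory gene covariates, the log2 fold changes that turned were, for S370A against WT, Six2 0.88, Six1 0.16, Tie1 0.0048 and Pten -0.10 (endothelial list adjusted p 0.910) and, for S370D against S370A, Sox9 -0.091, Slc48a1 -0.0021 and Pten 0.088. With the length trend removed Pten was 0.17 for S370D against WT. With both, S370A against WT gave Upk1b -0.038, Six2 0.79, Six1 0.14, Hoxa6 -0.052, Flt1 0.0010, Tie1 0.00067 and Pten -0.069 (endothelial list 0.906), S370D against WT gave Pten 0.17, and S370D against S370A gave Rptor 0.061, Col9a2 -0.012, Sox9 -0.11, Gstp1 -0.13, Slc48a1 -0.086 and Pten 0.24 (NRF2 list 0.909). With 9 libraries, Pten was -0.073 for S370A against WT (endothelial and homeobox lists 0.938 each), and S370D against S370A gave Gstp1 -0.11, Slc48a1 -0.043 and Pten 0.060 (NRF2 list 0.951). Without 1 library Pten ranged from -0.076 to 0.065 for S370D against WT. It ranged from 0.017 to 0.18 for S370A against WT and from -0.21 to -0.035 for S370D against S370A. The cause was not tested for any of these. At this depth, with 4 libraries per label, 42, 44 and 58% of simulated 2-fold changes were recovered in the 3 comparisons, and depth alone was not varied.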

Other observations

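Apart from the gene lists, the genes in this part were chosen after their values were seen. All 33 S phase genes and all 32 G2/M genes were higher in S370D than in S370A, with medians of 0.53 and 0.99 on the log2 scale, but the members of each list moved together (correlations of 0.743 and 0.843) and neither passed (camera adjusted p = 0.853 for both). S370D replicate 1 carried both, since without it 17 of 33 S phase genes (median 0.035) and 5 of 32 G2/M genes (median -0.31) were higher. The proliferation marker gene Mki67 held 73.1 CPM in S370D replicate 1 and 3.23 to 29.9 CPM in the other 11 libraries. Extracellular matrix genes were higher in S370D than in S370A for 32 of 36 members (median 0.33, adjusted p = 0.853), and without S370D replicate 4 for 28 of 36 members (median 0.14).

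Msmb, which encodes the prostate secretory protein beta-microseminoprotein, held 506 ± 459 CPM in WT, 457 ± 521 CPM in S370A and 3224 ± 2064 CPM in S370D (SD, n = 4 each). All 4 S370D libraries (1516 to 6132 CPM) lay above all 8 others (4.42 to 953 CPM), and edgeR did not call the difference (adjusted p = 0.713 against WT and adjusted p = 0.735 against S370A). How many other genes separate in this way was not counted. The lowest values were those of S370A replicates 1 and 2 (4.42 and 8.75 CPM) and WT replicate 2 (25.6 CPM). These libraries also had the highest scores on the first principal component. Whether a mix of gland parts or the label gave the Msmb difference was not tested. In S370A replicate 4 the Y-linked gene Eif2s3y held 8.12 CPM, against 23.0 to 48.3 CPM in the other 11 libraries, while Ddx3y held 57.0 CPM there.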
